A study of Mus musculus with 6 samples.

How the data were processed

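Bulk RNA sequencing was done on 6 tumours that B16F10 cells, a mouse melanoma line, had formed in male C57BL/6 mice. Per the labels, the mice were 6 weeks old, the cells were injected under the skin of the left hind leg in 200 µL of saline, and tumours were taken on day 19. The labels give 3 control tumours and 3 tumours of cells overexpressing YKL-40, the product of the gene Chi3l1. They do not state which vector the control cells carried, nor from which species the overexpressed sequence came. Libraries were made from 2 µg of RNA with the TruSeq RNA v2 kit, per the labels' protocols. That kit keeps no strand, so reads of genes that overlap on opposite strands were not told apart.

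The deposited table holds 1 FPKM value (fragments scaled to transcript length and to the depth of the library) per gene and library, for 20938 genes. The submitters' processing notes name bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma, with the mouse genome build mm10, without saying which of them made which values. The values of 16066 genes have more than 6 decimals in at least 1 library. How transcripts were combined into 1 value per gene is not given in the sources used here, and neither is the annotation. Of the genes, 4521 were at 0 in all 6 libraries. Total read numbers are unknown. The depth of each library was therefore only estimated relative to the first control, and no counting interval could be given. The estimate is the most common ratio of values among genes below 0.3 FPKM in every library, taken as the ratio of 1 read. Ratios far from 1 were left out, so a large difference in depth could not show. Columns of all 6 libraries were used, and no sample was left out.

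Groups were taken from the labels. Values were used as log2(FPKM + 1), which understates the changes of genes with low values. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 11241 in all. The difference between the YKL-40-labelled and the control libraries was tested with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend over expression, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided. The labels do not state that the 3 libraries of a group came from separate mice, so the p-values measure only the spread between these samples.

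For gene groups, 36 lists were fixed, and the 28 of them with at least 5 tested members were tested with camera of limma, with its preset correlation of 0.01 between genes, and adjusted over the lists. Camera compares a list with all other tested genes. It was repeated with the correlation estimated from the data, and the lists were also tested with fry of limma, which does not compare with the other genes. For the members of a list, p-values were adjusted over all tested genes and, separately, over the list alone. A member is said to have risen or fallen only after the adjustment over all genes, and where the list alone was used the text says so. These choices, the lists and the rule for naming genes were made before the data were examined.

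Genes were named by a rule. It takes Chi3l1, and the 8 largest increases and the 8 largest decreases past the threshold with groups that do not overlap, leaving out genes known only by a clone or model name. It also takes the 3 tested members of lowest p in each list that was called or had a member past the adjustment over the list alone, and the most abundant member of every other tested list. Of the genes the rule takes, 1 is not reported here. Any other gene is named as chosen after its values were seen. Gene positions came from a RefSeq table of assembly GRCm38.p6, the primary assembly of mm10, in which 20866 of the 20938 identifiers were found, 20721 of them by symbol.

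The testing procedure was tested on simulated data of 11241 genes in 5 runs. It recovered 78.4% of the genes changed by 1 on the log2 scale and 97.2% of those changed by 2, and 5.55% of its calls were false. The changed genes were drawn at random with the spread of all tested genes, so these shares do not hold for more variable genes. The real standard error was 0.49 for Gbp2 and 0.10 for Prc1, for example. In the real data, 0 of 22 interferon response genes passed over all genes, with a median change of 1.10. A raised list of MHC class I genes was called in 5 of 5 runs with the preset and in 5 of 5 with the estimated correlation, and of 135 unchanged lists 0 were called with either. The simulated genes vary independently of each other, so this does not show which correlation suits real lists. In the real data the estimated correlation was above the preset 0.01 for each of the 15 called lists. It ran from 0.0621 for p53 targets to 0.807 for MHC class II, with 0.666 for MHC class I and 0.722 for interferon response. The p-values with the preset may therefore be far too small.

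The alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at a mean of 5 FPKM, scaling to the same sum per library, scaling by the median of ratios, quantile normalization, 3 variants of the limma fit, the replicate number as a block, and leaving out each library in turn. A fit with the mean of the skeletal muscle list as a covariate was added after the data had been seen.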

Results

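RNA of whole melanoma tumours was sequenced to learn what overexpression of YKL-40, a secreted chitinase-like protein, does to tumours grown from B16F10 cells, and in particular to their proliferation. There were 3 control tumours and 3 tumours labelled YKL-40 overexpressing, all taken on day 19. Values are FPKM, given as mean ± SD (n = 3 libraries per group), and changes are YKL-40-labelled minus control on the log2 scale. The FPKM values summed to 469464, 479586 and 478426 in the controls and to 490955, 468605 and 472212 in the YKL-40-labelled libraries. Relative to the first control, the libraries had estimated depths of 1, 1.10 and 1.34 in the controls and 0.946, 1.20 and 1.12 in the YKL-40-labelled group. Between 10900 and 11301 genes reached 1 FPKM in a library. The first principal component took 57.0% of the variance and separated the groups, at -34.1, -19.1 and -12.2 against 26.4, 7.81 and 31.2. The mean correlation between libraries was 0.981 within the controls, 0.979 within the YKL-40-labelled libraries and 0.961 between the groups.

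The gene of YKL-40 itself, Chil1 in the file (Chi3l1; chromosome 1, 134182156 to 134190031, mm10), was near 0 in every library. The controls had 0.0644, 0 and 0.0242 FPKM and all 3 YKL-40-labelled libraries were at 0 (exact two-sided permutation p = 0.4, where 0.1 is the smallest p that 3 against 3 libraries allow). What these values mean depends on the species of the overexpressed sequence, which is not stated. Reads of a human or a recoded sequence need not map to this mouse gene, and its values would then not check the labels. For a mouse sequence, 0 FPKM in all 3 YKL-40-labelled libraries would go against overexpression on day 19. Which of these holds was not tested. All directions below rest on the labels alone. An effect of the YKL-40 label, where named below, includes any other difference between the injected cells, such as the vector. This design cannot tell such differences apart from YKL-40 itself. Among the chitinases and chitinase-like genes, 4 could be tested with limma and 0 changed at an unadjusted p under 0.05. Chil3, chosen after its values were seen, had 1.18 ± 1.57 and 1.59 ± 0.997 FPKM.

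Between the groups, 49 of 11241 tested genes changed, 41 of them higher and 8 lower in the YKL-40-labelled libraries. Genes of antigen presentation made up much of the increase. Of the 41 higher genes, 15 were on the lists of MHC class I or class II genes, and 5 were interferon-inducible GTPases. At an unadjusted p under 0.05 there were 979 higher and 1039 lower genes, and the groups of 2747 genes (24.4%) did not overlap, where chance gives 10%. The count of 49 depended on single libraries. It was 2 without control 1, 0 without control 2 (1345 at an unadjusted p under 0.05 in limma), 209 without control 3, 4 without YKL-40-labelled library 1 and 238 without library 2. It was 35 without library 3, of which 24 were among the 49. The count was 1 without a filter on low values and 1111 with array quality weights. Of the 15 gene lists called by camera with the preset correlation, 3 also passed with fry, and the other 12 did not (adjusted p from 0.0619 to 0.465). With the correlation estimated from the data, camera called 0 lists. With the skeletal muscle list as a covariate, chosen after the data were seen, the count of genes was 0 in limma (541 at an unadjusted p under 0.05).

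The series asks about proliferation, and the genes of cell division did not pass a test in the full data. Of 26 genes of G2 and mitosis, 0 passed in limma, over all genes or over the list alone, and 0 had an unadjusted p under 0.05. The list had a median change of -0.04 (adjusted p = 0.868), and of 0.04 without YKL-40-labelled library 1. Prc1 had 164 ± 7.56 FPKM in the controls and 162 ± 13.6 in the YKL-40-labelled libraries. Of 26 genes of G1 and S phase, 0 passed either adjustment in limma and 1 had an unadjusted p under 0.05 (list adjusted p = 0.806). Without YKL-40-labelled library 1 this list was called higher (adjusted p = 0.00472). Rrm2 had 80.9 ± 3.82 and 79.0 ± 4.52 FPKM. The mean log2 level of the G2 list varied more in the YKL-40-labelled libraries (5.16 ± 0.18) than in the controls (5.23 ± 0.10). With 3 libraries per group, a difference of the size of that spread or somewhat larger could be missed. These are RNA levels of whole tumours, and the number of dividing cells was not analysed here.

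MHC class I genes and the proteins that load them were higher in the YKL-40-labelled libraries. H2-K1 (chromosome 17, 33996012 to 34000619) rose from 99.3 ± 7.26 to 548 ± 181 FPKM, 5.52-fold. The immunoproteasome genes Psmb8 (chromosome 17, 34198195 to 34201454) and Psmb9 rose from 5.30 ± 0.780 to 80.8 ± 49.0 and from 4.09 ± 1.04 to 46.5 ± 22.98 FPKM. Their changes were 2.40, 3.55 and 3.14 on the log2 scale, with an adjusted p of 0.0303 for each. Of 18 list members, 10 rose over all genes and 17 passed with p adjusted over the list alone. The exception was Calr, with a change of 0.10. Calr and the next genes were chosen after their values were seen. Tap1 rose by 2.32 and B2m had a change of 1.31 that passed over the list alone. The list rose with a median change of 1.75 (adjusted p = 1.5e-23, adjusted p = 0.206 with an estimated correlation, and 0.0474 with fry). The same 17 passed over the list alone in each fit without 1 library, while the count over all genes was 0 without control 1, control 2 or YKL-40-labelled library 1. The H2 class I genes are close in sequence, so which of them rose is uncertain.

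MHC class II genes showed larger changes. Cd74 (chromosome 18, 60803849 to 60812652) rose from 32.7 ± 9.50 to 597 ± 440 FPKM. H2-Aa rose from 11.7 ± 4.22 to 211 ± 137, H2-Eb1 from 6.46 ± 1.80 to 108 ± 62.6 and H2-Ab1 from 7.95 ± 3.23 to 115 ± 60.1 FPKM. These changes were 3.94, 3.89, 3.70 and 3.60, with an adjusted p of 0.0381 for H2-Aa and 0.0303 for the others. Of 8 tested members, 5 rose over all genes and 8 passed over the list alone, in the full data and in each fit without 1 library. The count over all genes was 0 without control 1, control 2 or YKL-40-labelled library 1. The median change was 3.13 (adjusted p = 7.7e-13, adjusted p = 0.206 with an estimated correlation, and 0.0474 with fry). Dendritic cell markers were higher as a list (median 1.34, adjusted p = 4.2e-06, adjusted p = 0.206 with an estimated correlation). Of 8 tested markers, 0 passed over all genes in limma (6 at an unadjusted p under 0.05), and 6 passed over the list alone, among them Irf8 (2.05), Ccr7 (1.72) and H2-DMb2 (1.70). The median was 0.85 without a filter. The count of 6 was 10 of 11 without control 3. Over all genes, 2 passed without control 3 and 4 without YKL-40-labelled library 2.

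**Figure D1:**
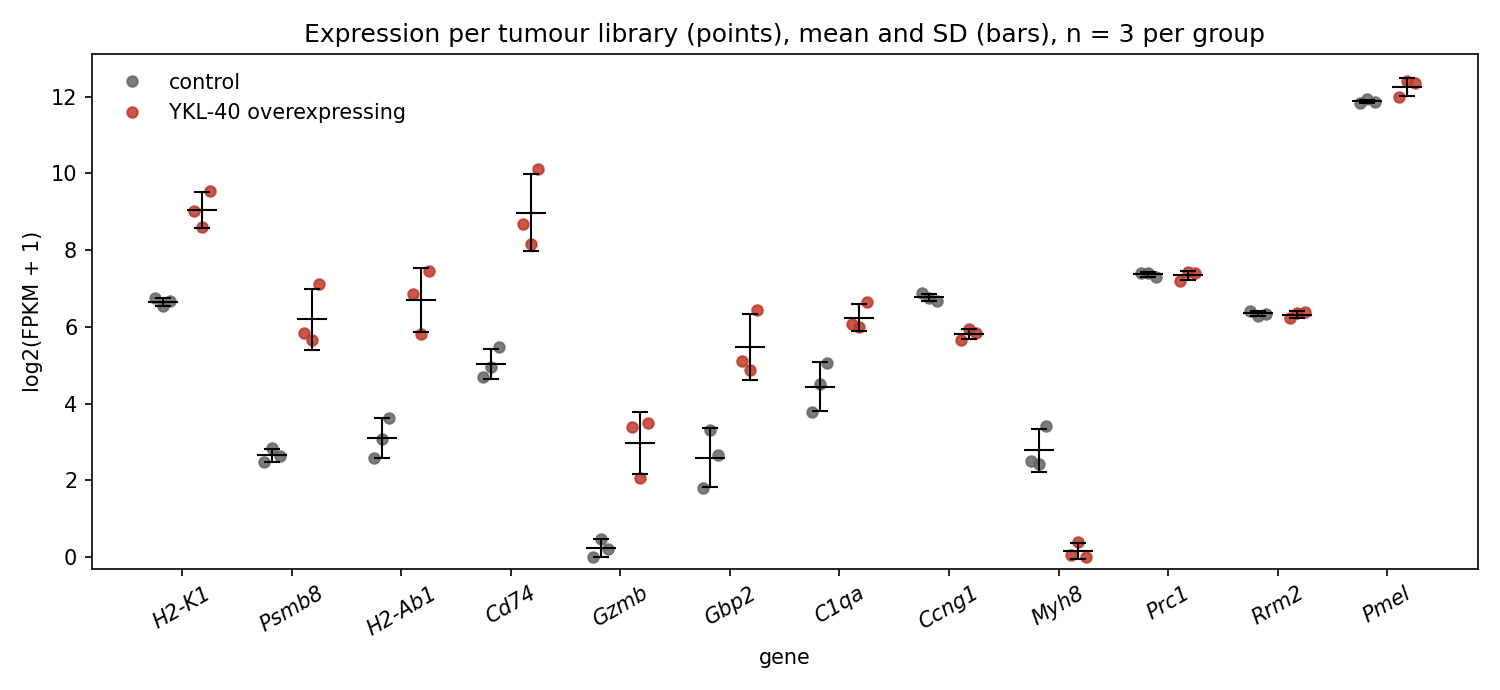
Levels of 12 named genes as log2(FPKM + 1), with 1 point per library and bars for the mean and SD of each group (n = 3; grey, control; red, YKL-40-labelled). H2-K1 rose by 2.40 and Cd74 by 3.94, while Myh8 fell by 2.62.

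Interferon-stimulated genes were higher as a list. Of the 22 genes on the interferon response list, all had a change above 0, and 20 passed over the list alone. Over all genes, 0 passed in limma, with 20 at an unadjusted p under 0.05, and 8 passed without YKL-40-labelled library 2. Gbp2 went from 5.61 ± 3.25 to 49.2 ± 32.2 FPKM (2.87) and Bst2 from 101 ± 30.1 to 281 ± 75.5 (1.48). The list had a median change of 1.10 (adjusted p = 4.3e-18, adjusted p = 0.244 with an estimated correlation). With the skeletal muscle level as a covariate, the median was 0.40 and 0 members passed over the list alone in limma. Among the largest single increases were Tgtp1, from 7.20 ± 4.97 to 141 ± 114 FPKM (19.7-fold, adjusted p = 0.0472), and Tgtp2, from 12.6 ± 8.57 to 178 ± 127 (3.68, adjusted p = 0.0484), both GTPases. Apol9a rose from 9.31 ± 6.15 to 124 ± 55.8 FPKM (3.68, adjusted p = 0.0381). Tgtp1 and Tgtp2 are near copies of each other, and so are Apol9a and Apol9b, so how reads were shared within each pair is uncertain. Neither Tgtp1 nor Tgtp2 passed with a pseudocount of 0.01, with median of ratios scaling or without a variance trend (adjusted p from 0.0537 to 0.0584). Tgtp1, Tgtp2 and Apol9a also lost their calls without control 2, where 0 of all tested genes passed. Only 1 gene passed without a filter and 2 without control 1.

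Markers of cytotoxic lymphocytes were low in the controls and higher as a list in the YKL-40-labelled libraries. Gzmb rose from 0.182 ± 0.194 to 7.62 ± 3.89 FPKM (2.75, adjusted p = 0.0400) and Prf1 from 0.165 ± 0.125 to 4.55 ± 2.38 (2.16, adjusted p = 0.0444). Gzmc, a close relative of Gzmb, went from 0.0535 ± 0.0559 to 3.30 ± 3.04 (1.81) and passed over the list alone. All 5 tested members of the natural killer and cytotoxic list passed over the list alone (median 1.81, adjusted p = 7.9e-07, adjusted p = 0.206 with an estimated correlation). Without YKL-40-labelled library 1 or 3, too few members were left for a list test. The count over all genes went from 2 to 0 without control 1, without control 2 and without either of those libraries, and to 6 without library 2. With a pseudocount of 0.01 neither the gene Gzmb (adjusted p = 0.0896) nor the gene Prf1 (0.0727) passed, and Prf1 did not with median of ratios scaling (0.0540). The list's median was 4.13 and 5.18 with pseudocounts of 0.1 and 0.01, and 0.45 without a filter, which adds genes near 0. Only 3 T cell markers reached the filter, and all 3 passed over the list alone, Cd8a (1.79), Cd5 (1.26) and Thy1 (1.00, but 0.63 without control 1), while 0 passed over all genes in limma (3 at an unadjusted p under 0.05). Over the list alone 1 passed without YKL-40-labelled library 3, and over all genes 2 passed without library 2. Of 17 T cell markers above 0, all 17 had higher values in every YKL-40-labelled library than in any control, and 14 of them lay below the filter. Markers of 1 cell type vary together, so these are not 17 separate observations. Among all tested genes, the groups of 24.4% did not overlap in either direction.

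Immune checkpoint genes rose as a list (median 0.83, adjusted p = 5.8e-05, adjusted p = 0.206 with an estimated correlation). Cd274, the gene of PD-L1, went from 7.30 ± 1.55 to 22.1 ± 8.94 FPKM (1.43), Cd80 changed by 0.83 and Havcr2 by 0.53. Of 7 tested members, 0 passed over all genes in limma (6 at an unadjusted p under 0.05), and 6 passed over the list alone. That number was 1 without control 1 or without YKL-40-labelled library 3, and 2 without library 1.

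Macrophage markers also rose as a list, with a median change of 1.14 (adjusted p = 5.7e-09, adjusted p = 0.287 with an estimated correlation). C1qa went from 22.2 ± 9.82 to 76.2 ± 20.0 FPKM (1.80), Spi1 changed by 1.36 and Aif1 by 1.14. Of 19 tested markers, 0 passed over all genes in limma (12 at an unadjusted p under 0.05), and 11 passed over the list alone. That count was 6 without control 1, 4 without control 2, 7 without YKL-40-labelled library 1, 6 without library 2 and 4 without library 3. It was 4 without a filter, 16 without control 3, 15 with the replicate number as a block and 14 with array quality weights. Over all genes 8 passed without control 3 and 2 without library 2. Genes of alternative activation rose as a list (median 1.23, adjusted p = 3.6e-06, adjusted p = 0.206 with an estimated correlation). Retnla went from 0.170 ± 0.243 to 9.53 ± 9.27 FPKM (2.83), Clec10a changed by 1.70 and Mgl2 went from 0.202 ± 0.0782 to 2.02 ± 1.26 FPKM. They were among the 5 of 10 members that passed over the list alone, 8 without control 3, while 0 passed over all genes in limma (5 at an unadjusted p under 0.05), 1 without control 3 and 3 without library 2. The median was 0.63 without a filter. Arg1, chosen after its values were seen, had a change of -0.44 that did not pass.

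Inflammatory genes under NF-kB rose as a list, by a median of 0.82 (adjusted p = 5.5e-07, adjusted p = 0.287 with an estimated correlation), and of 1.29 with a pseudocount of 0.01. Icam1 changed by 1.48, Nfkbiz by 0.82 and Birc3 by 0.81. Of 17 members, 8 passed over the list alone, and 0 passed over all genes in limma (11 at an unadjusted p under 0.05). The 8 became 0 without control 1, control 2, or YKL-40-labelled library 1 or 3, and 12 without control 3 and 13 without library 2. The 8 also became 0 without a filter, and 14 with array quality weights. Over all genes, 3 passed without control 3 and 2 without library 2. Neutrophil markers, 3 of which could be tested, had 0 members past either adjustment in limma and 0 at an unadjusted p under 0.05. The same held for the 1 tested B cell marker, the 1 tested skin keratinocyte marker and the 2 tested platelet markers. Without control 3, 1 neutrophil and 1 platelet marker were higher over their lists alone. No marker of mast cells or eosinophils reached the filter.

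**Figure D2:**
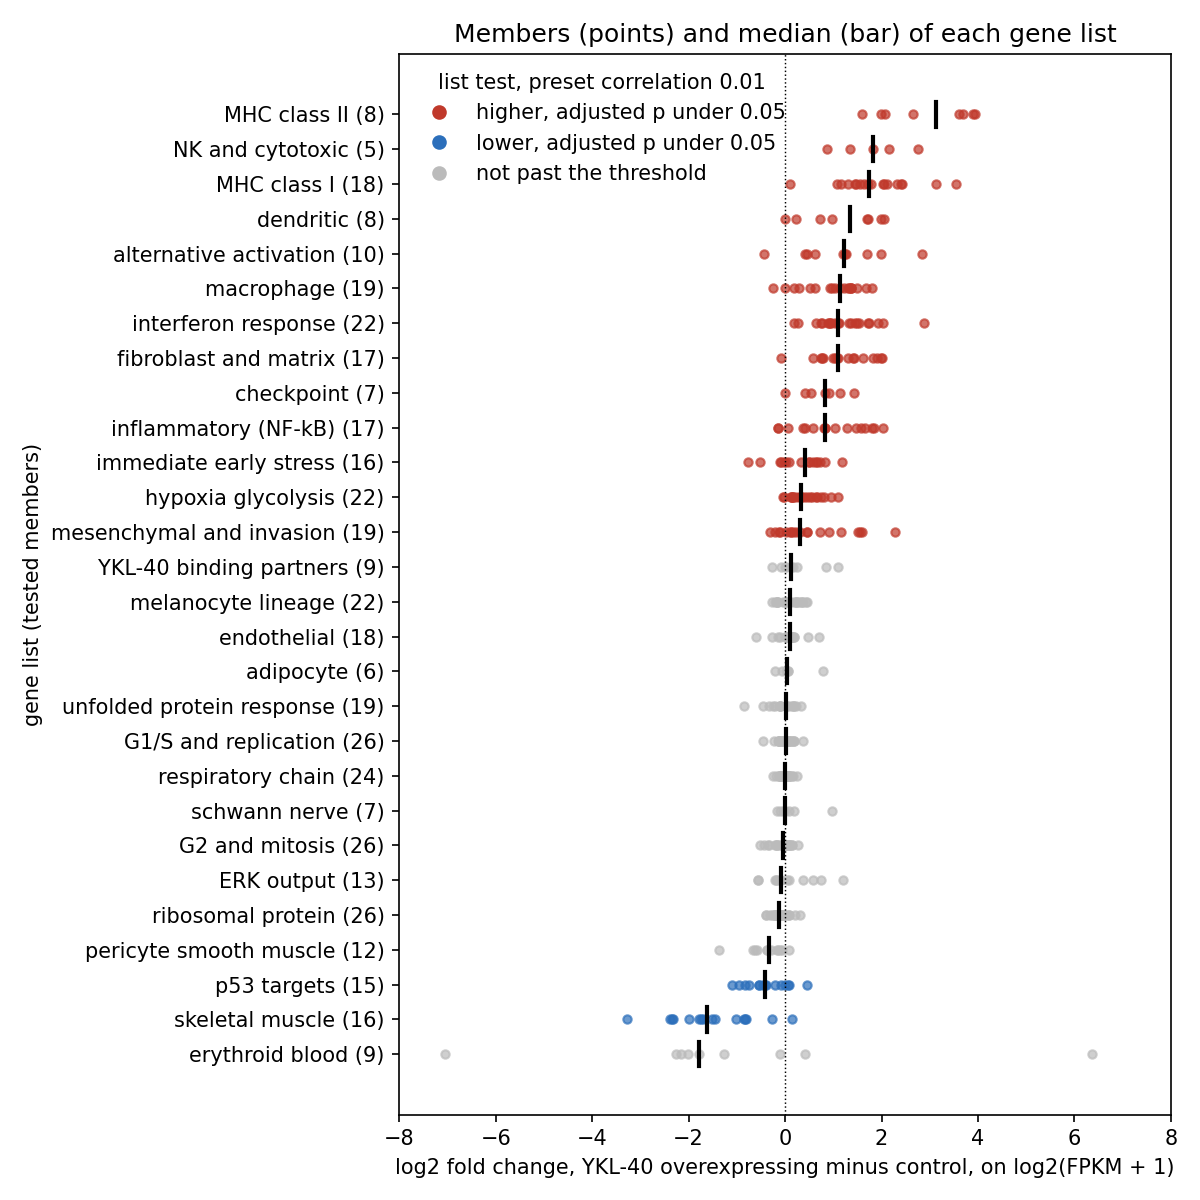
Log2 changes, YKL-40-labelled minus control, of the tested members of each tested gene list (points) and their median (bars), in red for lists called higher and blue for lists called lower with the preset correlation, and in grey for the others. The median was 1.75 for MHC class I, 3.13 for MHC class II and -1.61 for skeletal muscle.

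Fibroblast and matrix genes were higher as a list (median 1.10, adjusted p = 7.9e-10, adjusted p = 0.287 with an estimated correlation). The median was 0.65 without control 1. Lum went from 1.92 ± 0.650 to 8.10 ± 2.92 FPKM (1.61), Fbln1 from 19.1 ± 2.04 to 28.9 ± 2.04 (0.57) and Pdgfra from 2.30 ± 1.68 to 7.49 ± 2.66 (1.43). Of 17 members, 8 passed over the list alone and 0 over all genes in limma (12 at an unadjusted p under 0.05). That 8 became 2 without control 1, control 2, or YKL-40-labelled library 1 or 3, and 16 without control 3, and over all genes 5 passed without control 3 and 4 without library 2. Mesenchymal transition genes rose as a list (median 0.31, adjusted p = 0.00587, adjusted p = 0.456 with an estimated correlation), though 0 of 19 passed in limma by either adjustment (5 at an unadjusted p under 0.05, 4 of them higher). Mmp3 had a change of 2.29, Tgfbi of 1.51 and Plau of 0.91, which was 0.55 without control 1. Without control 1 the list was not called (median 0.10, adjusted p = 0.0808), and without control 3 its median was 0.59, while 7 members were higher over the list alone without control 3, 3 without YKL-40-labelled library 2 (1 lower) and 1 without library 1. Over all genes, 1 passed without control 3 and 1 without library 2.

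Hypoxia and glycolysis genes rose by a small amount as a list (median 0.33, adjusted p = 5.2e-07, adjusted p = 0.364 with an estimated correlation). Without YKL-40-labelled library 1 the median was 0.21. Ndrg1 went from 22.5 ± 9.37 to 47.1 ± 2.14 FPKM (1.10), Hk2 from 102 ± 21.4 to 159 ± 17.2 (0.65) and Kdm3a from 43.4 ± 5.11 to 57.4 ± 4.25 (0.40). Of 22 genes, 5 passed over the list alone and 0 over all genes in limma (9 at an unadjusted p under 0.05). The 5 became 0 without control 1, control 2, or YKL-40-labelled library 1 or 3, and 9 without library 2, and over all genes 2 passed without control 3. The 5 also became 0 without a filter, without a variance trend and with the replicate number as a block, and 8 with array quality weights. Immediate early and stress genes were called as a list too (median 0.42, adjusted p = 0.00518, adjusted p = 0.463 with an estimated correlation), but not without control 1 (median 0.24, adjusted p = 0.156). Without YKL-40-labelled library 1 the median was 0.18, and with a filter at a mean of 5 FPKM 0.27. Fos changed by 1.18, Zfp36 by 0.73 and Junb by 0.83. Of 16 genes, 2 passed over the list alone, 7 without control 3, 3 without YKL-40-labelled library 2 and 0 higher in each of the other fits without 1 library. Without control 1, 1 was lower. Over all genes 0 passed in limma, with 4 at an unadjusted p under 0.05.

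Targets of ERK signalling went both ways. Over the list alone, Ier3 (1.21) was among 2 of 13 that were higher, and Spry4 (-0.57) and Etv5 (-0.55) were lower, while 0 passed over all genes in limma (5 at an unadjusted p under 0.05, 3 of them higher). Their median was -0.09 and their mean 0.09, and the list was not called (adjusted p = 0.868). Without control 1, control 2 or YKL-40-labelled library 3, 0 passed over the list alone. Without library 1 and without library 2, 1 was higher and 1 lower, and without library 2, 1 rose over all genes.

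Targets of p53 fell as a list, by a median of 0.42 (adjusted p = 6.7e-04, adjusted p = 0.206 with an estimated correlation, and 0.0474 with fry). Of 15 members, 11 had a change below 0 and 1 fell over all genes. That gene, Ccng1 (chromosome 11, 40748552 to 40755309), fell from 108 ± 7.62 to 55.5 ± 5.25 FPKM (-0.95, adjusted p = 0.0303). Gdf15 (-0.82) and Aen (-0.53) were among the 7 members that were lower over the list alone, a count of 1 without YKL-40-labelled library 3. Over all genes, 0 passed without control 1, control 2, or library 1 or 3. Without library 2, 2 fell over all genes and 2 others were higher over the list alone. With skeletal muscle as a covariate the median was -0.23 and the list was not called (adjusted p = 0.111). Some of the best known targets did not pass. Cdkn1a, chosen after its values were seen, had 125 ± 16.5 and 133 ± 43.9 FPKM.

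Skeletal muscle genes fell as a list, by a median of 1.61 (adjusted p = 2.4e-08, adjusted p = 0.287 with an estimated correlation), and 0 of 16 members passed over all genes in limma (13 at an unadjusted p under 0.05). The median was -2.62 with a pseudocount of 0.01 and -0.95 without a filter. Tnnt3 went from 30.3 ± 22.7 to 2.49 ± 3.03 FPKM (-3.27), Mylpf from 16.1 ± 9.09 to 2.63 ± 2.68 (-2.35) and Ttn from 8.84 ± 5.12 to 1.80 ± 1.07 (-1.74). Over the list alone 13 were lower, 12 or 13 in each fit without 1 library, and over all genes 2 without YKL-40-labelled library 2. The list's mean log2 level was 2.66, 2.03 and 3.38 in the controls and 1.11, 1.66 and 0.77 in the YKL-40-labelled libraries. Myh8 (chromosome 11, 67277124 to 67308634), the myosin of newborn muscle, fell from 6.24 ± 3.04 to 0.124 ± 0.175 FPKM (-2.62, adjusted p = 0.0303), a call that the gene Myh8 lost with a pseudocount of 0.01 (0.0794). Myl4, an embryonic myosin light chain, fell from 4.08 ± 1.34 to 0.604 ± 0.0786 (-1.63, adjusted p = 0.0303). Neither Myh8 nor Myl4 is on the skeletal muscle list. Both lost their calls without a filter, without control 1 and without control 2, where 0 genes were lower. As 72.1% of the variance of the muscle level lay between the groups, a fit with this level as a covariate cannot separate it from the labels. In that fit, 9 of 18 MHC class I and 4 of 8 MHC class II genes passed over the list alone, and 0 members of the other called lists did. This does not mean that muscle accounts for those lists, as the median was larger in that fit for fibroblast (1.51), macrophage (1.62), alternative activation (1.52), mesenchymal transition (0.82), immediate early (0.75) and hypoxia (0.44) genes, and each of these lists was still called.

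The other genes that fell were not on a list either. Col28a1, a collagen, fell from 11.8 ± 3.27 to 1.28 ± 0.671 FPKM (-2.49), Dcaf8l from 20.0 ± 1.83 to 6.03 ± 1.62 (-1.60) and Sema5a from 11.6 ± 1.52 to 4.25 ± 0.686 (-1.27), each with an adjusted p of 0.0303. Cpt1c, a brain form of carnitine palmitoyltransferase, fell from 5.94 ± 0.833 to 2.61 ± 0.0339 FPKM (-0.94, adjusted p = 0.0400). Nudt6 fell from 7.60 ± 0.0796 to 4.44 ± 0.318 (-0.66, adjusted p = 0.0484). The gene Nudt6 did not pass with a pseudocount of 0.01 (adjusted p = 0.0568), a filter at a mean of 5 FPKM (0.0609) or median of ratios scaling (0.0728). In the fits without a filter, without control 1 and without control 2, 0 genes were lower. Col28a1, Dcaf8l, Sema5a, Cpt1c and Nudt6 therefore all lost their calls there. Only 2 genes were lower without YKL-40-labelled library 1, and 2 without library 3.

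Rnf146, a ubiquitin ligase gene named after its values were seen, had the lowest p of all genes. It rose from 10.9 ± 0.669 to 37.0 ± 3.75 FPKM (1.67, adjusted p = 0.00738). It overlaps Echdc1 (chromosome 10, 29298144 to 29346661), whose change was -0.44 (adjusted p = 0.0950). Of the reported partners and receptors of YKL-40, the gene Lgals3bp rose from 48.3 ± 1.93 to 87.6 ± 8.30 FPKM (0.84, adjusted p = 0.0303) and was the only one of 9 to pass by either adjustment. Over all genes it did not pass without control 1 (adjusted p = 0.0946), control 2 (0.111), or YKL-40-labelled library 1 (0.107) or 3 (0.0528), and without control 3, 2 of the 9 passed. Lgals3 changed from 12.8 ± 7.72 to 25.6 ± 0.748 (1.11, but 0.67 without control 1) and Cd44 from 416 ± 11.3 to 456 ± 42.0, and neither passed. The list of partners was not called (median 0.13, adjusted p = 0.0536), but it was called when the values were scaled to the same sum per library (adjusted p = 0.0490), with quantile normalization (0.0297), with a filter at a mean of 5 FPKM (0.0302), without control 3 (0.0142) and without YKL-40-labelled library 2 (0.0400). The median of the list was 0.03 without control 1 and 0.08 without control 2, but 0.19 without YKL-40-labelled library 2.

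The alpha globin copies Hba-a1 and Hba-a2 went in opposite directions, while the beta globins Hbb-bs, Hbb-bt, Hbb-b1 and Hbb-b2 had changes below 0. The gene Hba-a1 rose from 0.547 ± 0.914 to 139 ± 106 FPKM (6.37, adjusted p = 0.0303), while its near copy Hba-a2, too variable to pass, went from 702 ± 558 to 25.4 ± 44.1 (-7.05, adjusted p = 0.0965). Hba-a1 did not pass without control 1 (adjusted p = 0.0931) or control 2 (0.0653), or with a pseudocount of 0.01 (0.0727). Hba-a2 was at 0 in YKL-40-labelled libraries 2 and 3, where Hba-a1 had 104 and 54.7 FPKM. In the controls Hba-a1 had at most 1.60 FPKM. The call of Hba-a1 does not show a rise in alpha globin, as how reads were shared between the copies is uncertain. Their sum was 703 ± 558 in the controls and 164 ± 149 in the YKL-40-labelled libraries, and the beta globins summed to 845 ± 635 and 149 ± 107. Alas2 went from 15.1 ± 11.4 to 2.53 ± 1.23 FPKM (-2.02) and, with Hba-a2, was lower over the list alone, a count of 2 that was 4 without control 1 and without YKL-40-labelled library 1. The red cell list of 9 tested genes was not called (adjusted p = 0.382), except without YKL-40-labelled library 1, where it was lower (adjusted p = 0.0323) and 1 gene fell over all genes. Without library 2, 2 genes were higher over the list alone.

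The remaining lists were not called in the full data. Among 22 melanocyte lineage genes (median 0.11, adjusted p = 0.0591), 0 passed by either adjustment in limma and 3 had an unadjusted p under 0.05. Pmel had 3752 ± 122 and 4906 ± 753 FPKM (0.38, adjusted p = 0.222). The median was -0.01 without YKL-40-labelled library 2, 0.07 without library 3, 0.05 without control 3 and 0.21 without library 1. The list was called higher without control 2 (adjusted p = 0.0145), with a filter at a mean of 5 FPKM (0.0302) and without YKL-40-labelled library 1 (2.3e-04), where 3 genes passed over the list alone. Likewise 0 members passed in limma for ribosomal proteins (26 genes, median -0.12, adjusted p = 0.0840, 4 at an unadjusted p under 0.05), with Rplp0 at 4227 ± 338 and 3597 ± 365 FPKM. That list was called lower without control 1 (adjusted p = 0.00210), without YKL-40-labelled library 1 (4.4e-06), when scaled to the same sum per library (0.0490), with quantile normalization (0.0368) and with array quality weights (4.9e-05). The median was -0.20 without control 1 and -0.24 without YKL-40-labelled library 1, but -0.08 without control 2 and -0.05 without library 2. 0 members also passed in limma for pericytes and smooth muscle (12 genes, median -0.34, adjusted p = 0.0591, 3 unadjusted), with Mylk at 36.0 ± 4.70 and 33.2 ± 1.67. They were called lower without control 1 (adjusted p = 0.00301), without YKL-40-labelled library 2 (0.0155, 1 gene over the list alone) and with each of the 3 scalings (0.0352 to 0.0490). Their median was -0.68 without YKL-40-labelled library 2, and -0.21 without control 3 and without library 1. Endothelial genes (18, median 0.09, adjusted p = 0.191, 0 past either adjustment in limma, 2 unadjusted) held Eng at 60.0 ± 2.37 and 62.1 ± 12.7. They were called higher without control 3 (adjusted p = 3.8e-04, 1 gene over all genes and 2 over the list alone) and without library 1 (0.0175), while the median was -0.11 without control 1 and -0.01 without library 2. Adipocyte genes (6, median 0.03, adjusted p = 0.386, 0 past either adjustment in limma, 1 unadjusted) held Fabp4 at 75.2 ± 16.7 and 72.6 ± 17.2, and 1 was higher over the list alone without control 3 or library 1. Their median was -0.09 without control 1, -0.02 without control 3 and -0.17 without library 3. It was 0.09 without control 2, 0.17 without library 1 and 0.10 without library 2.

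Genes of the respiratory chain (24, adjusted p = 0.868, 1 at an unadjusted p under 0.05) had 0 members past either adjustment in limma, with Atp5b at 1174 ± 73.7 and 1081 ± 61.0 FPKM. So did the unfolded protein response (19, adjusted p = 0.868, 0 unadjusted), with Hsp90b1 at 666 ± 41.1 and 673 ± 39.1, and Schwann cell and nerve genes (7, adjusted p = 0.386, 1 unadjusted), with Mbp at 111 ± 29.5 and 100.1 ± 28.4. Of the Schwann cell genes 1 was higher over the list alone without control 3 and without YKL-40-labelled library 1. The test pointed up for several uncalled lists whose median or mean did not. Median and mean were 0.01 and 0.00 for G1 and S phase, 0.01 and -0.07 for the unfolded protein response, 0.01 and 0.00 for the respiratory chain and -0.01 and 0.13 for Schwann cells. No gene made by the mitochondrial genome was in the table.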

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

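The muscle covariate was chosen after the results were seen, and the other alternatives before. The count of 49 genes (41 higher, 8 lower) moved with several settings. Without a filter 1 gene passed, 1 higher and 0 lower. With a filter at a mean of 5 FPKM, 4 were lower. With array quality weights 1111 passed, 665 higher and 446 lower. Leaving out 1 library gave 0 to 238 genes, 0 to 198 higher and 0 to 40 lower. None of the 49 genes changed sign in any alternative in which it was tested. Of them, 37 were tested at a mean of 5 FPKM and 48 in each fit without 1 YKL-40-labelled library.

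The replicate number as a replicate block gave 120 genes, 110 higher and 10 lower, and pericytes became a lower list (adjusted p = 0.0163). Residuals of libraries with the same number correlated at -0.0832, -0.185 and 0.0017, and those with different numbers at -0.137 to 0.204. The residuals of the 3 libraries of a group sum to 0, so these few values cannot decide whether the numbers pair the samples.

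With the muscle list mean as a covariate, 0 genes passed, 0 higher and 0 lower (541 at an unadjusted p under 0.05 in limma), and 15 lists were higher and 1 lower. Over the 49 genes the median ratio of standard errors was 1.87 and of changes 0.768, and 49 kept their sign. For some genes the error widened while the change stayed, as for Ccng1, from -0.95 (SE 0.11) to -0.97 (SE 0.22). For others the change shrank, as for Tgtp2, from 3.68 (SE 0.54) to 1.73 (SE 0.62), and Apol9a, from 3.68 (SE 0.46) to 2.38 (SE 0.73). Respiratory chain genes turned to a lower list, with a mean of -0.14 (adjusted p = 0.0399), and p53 targets were no longer called (0.111). Endothelial genes (adjusted p = 2.4e-06, mean 0.07 before and 0.60 with the covariate) and the YKL-40 partners (0.0166) became higher lists. The mean of the interferon list went from 1.23 to 0.45. The muscle list itself is fixed by this fit and was not counted.

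Of 28 tested lists, 13 were higher and 2 lower. With a correlation estimated from the data, 0 lists were called, 0 higher and 0 lower. There were 4 lower lists when the values were scaled to the same sum per library and 4 with quantile normalization. Without 1 library, 14 to 19 lists were called, 11 to 15 higher and 2 to 4 lower. At a mean of 5 FPKM the alternative activation, checkpoint, dendritic, natural killer and adipocyte lists had too few members to test.

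Correlations between libraries were 0.974, 0.974 and 0.946 (within controls, within the YKL-40-labelled group and between) with a pseudocount of 0.1. For Chi3l1 the change was -0.34 and -1.56 with pseudocounts of 0.1 and 0.01, -0.04 without a filter (adjusted p = 0.497) and between -0.06 and -0.02 without 1 library. The other alternatives were not run for it, since it lies below the filter. Of 1380 values for 78 named genes, 1164 were the same, 141 weaker, 75 stronger and 0 reversed. Most of the 78 did not pass over all genes in the full data, so this total does not measure how stable the calls were. In the fits without a filter, without control 1, without control 2 and with the muscle covariate, 22 of the 78 were weaker. Without YKL-40-labelled library 1, 21 were weaker.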

Other observations

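The tests of muscle dilution, of leukocytes of an unchanged mix, and of the muscle ratio without Tnnt2, Ncam1 and Eno3 were chosen after the results were seen. So were the gene families and single genes described first. All 16 tested interferon-inducible GTPases had a change above 0, with a median of 2.86 (adjusted p = 5.0e-21, adjusted p = 0.137 with an estimated correlation), and 5 passed over all genes. Among them were Gbp4 (3.52), Igtp (3.33) and Ifi47 (2.84). The type I interferon core genes had 18 of 18 changes above 0 with a median of 1.04 (adjusted p = 7.0e-15, adjusted p = 0.137 with an estimated correlation), and Oas2 (1.47) and Oas3 (1.92) passed over all genes. Complement genes had 17 of 17 above 0 with a median of 1.12 (adjusted p = 1.8e-12, adjusted p = 0.137 with an estimated correlation), and Cfb passed (2.00). Ifng itself was at 0.00717 ± 0.0124 FPKM in the controls and 0.393 ± 0.261 in the YKL-40-labelled libraries, below the filter.

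Cathepsins had 10 of 11 changes above 0 (median 0.40, adjusted p = 2.8e-05, adjusted p = 0.137 with an estimated correlation). Of 289 zinc finger genes named Zfp, 228 were below 0 (median -0.14, adjusted p = 2.8e-05, adjusted p = 0.367 with an estimated correlation), while 0 passed in limma and 45 were lower at an unadjusted p under 0.05. Their median was -0.17 scaled to the same sum, -0.11 by the median of ratios and -0.20 with quantile normalization. Other single genes that rose were Il2rb (2.60), Il1rl1 (1.81), Lyve1 (1.62), Ly86 (1.79) and Unc93b1 (0.97). The Y-linked gene Ddx3y had 2.10 ± 0.874 FPKM in the controls and 3.08 ± 0.998 in the YKL-40-labelled libraries, and its X-linked relative Ddx3x had 155 ± 22.7 and 133 ± 18.4.

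For the rise of MHC class I genes, less muscle would raise all tumour transcripts alike, but the list rose by 1.86 (SE 0.29) more than the melanocyte lineage list, which argues against it. A general rise in leukocytes stays open: on a list of 18 genes of all leukocytes, 0 of them on a fixed list and all 18 above the filter in these tumours, all 18 changes were above 0 (0 past adjustment over all genes in limma, 17 at an unadjusted p under 0.05), and MHC class I exceeded their mean change by only 0.37 (SE 0.45). The most abundant was Lcp1, at 86.5 ± 37.7 and 168 ± 14.2 FPKM. Whether it was only more leukocytes of the mix in the controls cannot be told apart from another mix: over the 3 controls the slope of MHC class I on these genes was -0.0097 (SE 0.0822), but with 1 degree of freedom its upper 95% limit of 1.04 includes the slope of 1 that such leukocytes would give. An effect of the YKL-40 label, through other leukocytes or through an interferon response of tumour cells, may remain and was not tested further.

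If the lower muscle genes came from different amounts of 1 and the same adult muscle, the log2 ratio of developing to adult muscle genes would stay alike. Its SD over the 6 libraries was 0.799, above the bound of 0.5 set before the result was seen. The test cannot decide on amount, as transcripts from other cells would also move this ratio. Tnnt2 alone made up 61.6 to 81.4% of the developing sum in the YKL-40-labelled libraries and 39.7 to 44.6% in the controls. Its own level was 15.2 ± 9.03 and 15.8 ± 8.70 FPKM. Which way the ratio differed depends on the genes: with all of them it was higher in 2 of the 3 YKL-40-labelled libraries (-0.59, -2.38 and -0.45, against -1.99, -1.64 and -1.98 in the controls), and without Tnnt2 and Ncam1 it was lower in all 3 (-4.02, -4.61 and -3.07, against -2.82, -2.52 and -2.96). Without Eno3 as well, the groups overlapped (-2.40, -3.88 and -1.55, against -2.46, -2.08 and -2.84). The SDs of 0.804 and 0.788 in these versions are therefore not the same finding repeated, and no direction between the groups is read from them. Different amounts of the same muscle, transcripts of these genes from other cells, muscle of another kind and an effect of the YKL-40 label stay open.

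For Rnf146, extra copies of its region in the overexpressing cells were tested. The 3 tested genes within 500 kb had a median change of -0.32 (SE 0.20), which argues against them. Extra copies of Rnf146 alone, reads shared with the overlapping Echdc1 and an effect of the YKL-40 label may remain, and none of these was tested.

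Over the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real 49, namely the real one, and the highest other gave 2. With 10 splits the share cannot go under 0.1.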
